A study of Homo sapiens with 11 samples.

How the data were processed

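RNA of MDA-MB-231 cells was measured on 11 Illumina 1-colour bead arrays. Per the labels, cells were transfected with a non-targeting control siRNA or with 1 siRNA against MASTL, and RNA was taken after 24 h or 48 h. There were 3 control and 2 MASTL siRNA arrays at 24 h, and 3 and 3 at 48 h. The replicate numbers were 1, 2 and 3 for 24 h controls, 1 and 3 for 24 h MASTL siRNA, and 1, 3 and 4 for each group at 48 h. Per the labels' protocols, total RNA was amplified to cRNA and biotin-labelled before hybridisation.

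The values used were the normalized log2 values deposited by the authors, 47321 probes on each array. Per the submitters' processing notes, lumi was used, with no version or role given. The values themselves showed that they had been normalized between arrays. The sorted values of each array differed from those of 24 h control replicate 1 by at most 0.000698. Every array had a median of 7.4039, and all values lay between 7.2365 and 14.512. Taking the scale as log2 rests on that range. Whether a plain log2 or a variance-stabilizing transform was applied is not stated, so folds near the floor understate the change. A second deposited table, with 11 columns of non-normalized signals and 11 of detection p-values, was not used, because its column names do not tie a column to a sample. The design had assumed those signals with background correction and detection p-values. The authors' normalized values were therefore tested as they stood, with a noise limit in place of detection p.

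The noise limit was set from the values. The most common log2 value, 7.357, was taken as the centre of the noise, the values below it were mirrored, and the 95th percentile of that mirrored noise, 7.409, was the limit. It was exceeded by 22839 probes on each array, the same number because the arrays share 1 set of sorted values. Probes above it on at least 2 of the 11 arrays were kept, 27315 in all. Gene names came from a platform annotation table, in which 30113 probes had 1 gene symbol, 8 had several and 17200 had none. Symbols were updated through the Entrez number for 30074 of them. A gene was represented by its probe of highest mean log2 value, and a probe with several symbols or none stood as a feature of its own. This gave 22144 features, 14025 of them named genes and 8119 not. For 41 of the genes named by the rule given below there were 55 other probes past the filter, of which 13 had the opposite sign at 24 h and 9 at 48 h.

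A linear model with a mean for each of the 4 groups was fitted to all 11 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, which left 7 residual degrees of freedom and added 1.67 by moderation. The comparisons were MASTL against control siRNA at 24 h, at 48 h and on average over both, the 48 h change minus the 24 h change, and 48 h against 24 h under control siRNA. A feature was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Gene lists were tested with camera (preset correlation 0.01), adjusted over the 25 lists of a comparison, with camera's estimated correlation and with fry, which does not compare a list with other genes. The lists held 460 entries of 438 distinct genes, of which 399 entries had a tested feature and 61 did not, and 20 of the 379 tested genes stood in more than 1 list. They covered MRTF-SRF targets, immediate early genes, YAP-TAZ targets, integrins and focal adhesion, extracellular matrix and remodelling, the PP2A-B55 and Greatwall axis, G2-M and mitosis, G1-S and DNA replication, histone genes, p53 targets, interferon response, NF-kB and inflammatory cytokines, mesenchymal markers, epithelial markers, TGF-beta SMAD targets, cholesterol synthesis, ATF4 and amino acid stress, endoplasmic reticulum chaperones, hypoxia and glycolysis, the BCL2 family, NRF2 targets, luminal breast markers, leukocyte and endothelial markers and reference genes. The result of 1 further list, counted among the 25, and of its called member is left out of the text. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

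The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named MASTL, the 8 genes of largest rise and of largest fall at each time among called genes whose groups did not overlap, up to 3 called members per list, or, for a list without any, the 2 of highest mean level. For the average it named the 5 genes of smallest adjusted p in each direction. For the difference between the times and for time under control siRNA it named called genes, of which there were 0.

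Whether replicate numbers pair the arrays was checked from the correlation, across features, of the deviations of same-numbered arrays from their group means. At 48 h the correlations were 0.693, 0.549 and 0.773 for replicates 1, 3 and 4, so the numbers were taken to pair those arrays, on the evidence of the values and not of the labels. At 24 h only 2 pairs exist (0.104 and 0.47), which is too few to decide. Across times the correlations were -0.0842 and -0.205 for controls and 0.119 and 0.109 for MASTL siRNA.

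The fit was tested on simulated data with 50 changed features at each log2 size among 22144. At 24 h it recovered 60% of changes of 0.25, 90% of 0.5, 96% of 1 and 100% of 2, with 8 false calls. At 48 h it recovered 64%, 94%, 96% and 98%, with 12 false calls. For the average it recovered 76%, 94%, 96% and 100%, with 10 false calls. With no change simulated, it made 0 calls for the difference between the times and for control time. The simulated noise was drawn independently for each feature and array. It lacks the correlation between genes and between same-numbered arrays seen in these data, so these rates are not error rates of the real arrays.

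Alternatives tried were no filter, probes above the limit on all 11 arrays, a 99th percentile noise limit, every probe as a feature, cyclic loess, only the 2 groups compared, the replicate number as a fixed block, a block within each time or a random block, array weights, an intensity trend with robust moderation, a minimum change of 1.5-fold, other adjusted p thresholds, other list tests, and leaving out each array or each replicate number. Matches of the siRNA seed to 3' untranslated regions were not analysed here, because the reference tables used hold no such sequence.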

Results

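The data were whole-genome expression profiles of MDA-MB-231, a cell line from a triple-negative breast adenocarcinoma, transfected with a control siRNA or with 1 siRNA against MASTL. MASTL encodes the Greatwall kinase, which acts through ENSA and ARPP19 to restrain the phosphatase PP2A-B55 at entry into mitosis. The question put by the series was what MASTL silencing does to RNA levels across the genome in these cells. RNA was taken at 24 h for 3 control and 2 MASTL siRNA arrays and at 48 h for 3 and 3, making 11 one-colour bead arrays. Each array reported 47321 probes, of which 22839 lay above the noise limit of 7.409 on the log2 scale. The number of arrays limits the precision of every value. The labels number the replicates but do not say that they are separate cultures, so p-values measure only the spread between arrays. Within a group, the Pearson correlation across the tested features of any pair of arrays lay between 0.9904 and 0.9969.

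MASTL RNA was lower in every MASTL siRNA array than in every control array at both times. At 24 h it averaged 7.65 ± 0.053 (SD, n = 2) against 8.71 ± 0.054 (n = 3) on the log2 scale, a log2 change of -1.05 (SE 0.091, limma adjusted p = 0.00137), or 2.08-fold lower. At 48 h it averaged 7.58 ± 0.077 (n = 3) against 8.52 ± 0.18 (n = 3), a log2 change of -0.93 (SE 0.082, adjusted p = 0.00117), or 1.91-fold lower. Its other probe, nearer the floor, read 7.47 ± 0.088 against 8.09 ± 0.16 at 24 h and 7.45 ± 0.037 against 8.03 ± 0.086 at 48 h. The silenced level lay close to the noise limit of 7.409, where the scale is compressed, so these folds understate the loss of transcript.

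**Figure D1:**
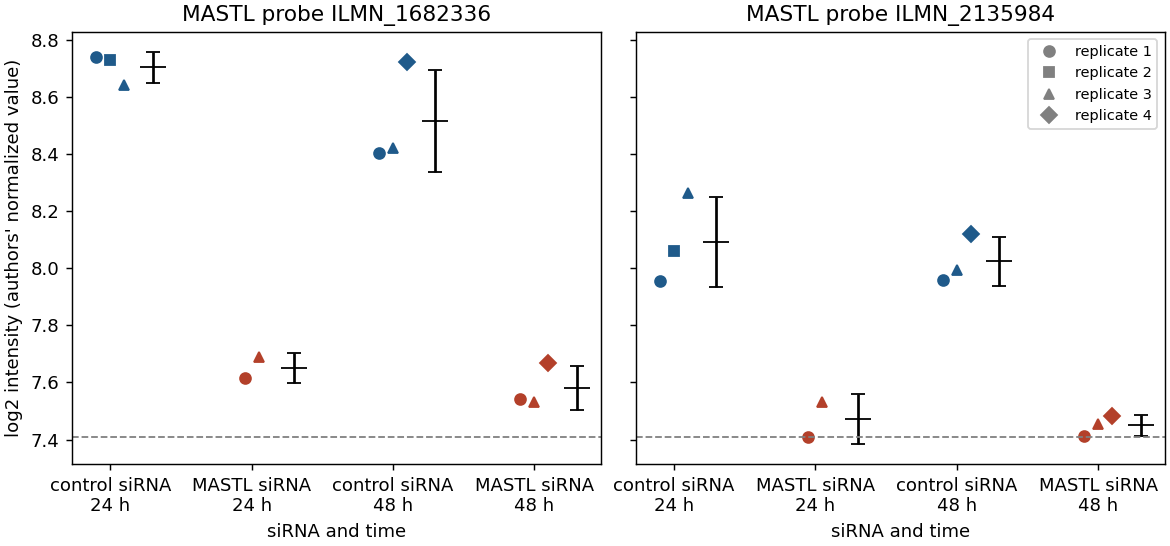
MASTL level (log2 value) on each array for both MASTL probes, by siRNA and time, with group means and SD. All MASTL siRNA arrays lie below all control arrays for both probes; for the brighter probe the group means are 7.65 against 8.71 at 24 h and 7.58 against 8.52 at 48 h.

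With 1 siRNA, the changes below cannot be assigned to loss of MASTL alone. At 24 h under the MASTL siRNA, the deepest fall was that of SLC2A3, which encodes the glucose transporter GLUT3. It dropped from 10.92 ± 0.24 (SD, n = 3) to 9.08 ± 0.26 (n = 2), 3.58-fold lower (log2 change -1.84, SE 0.23, adjusted p = 0.0086). CDK6, a cyclin-dependent kinase of the G1 phase, was 2.67-fold lower (log2 change -1.42, SE 0.15, adjusted p = 0.00389). GTF2E2, a subunit of the general transcription factor TFIIE, fell from 9.78 ± 0.048 (n = 3) to 8.56 ± 0.012 (n = 2), a log2 change of -1.22 (SE 0.055, adjusted p = 6.83e-05). PACSIN2, which binds and bends membranes (-1.27), the tropomyosin TPM4 (-1.26), the mitochondrial protein HIGD1A (-1.25) and the translation factor DENR (-1.24) fell as well, each with adjusted p = 0.000582. VMA21, an assembly factor of the vacuolar proton pump, changed by -1.21 (SE 0.095, adjusted p = 0.000864). The DENR probe used here was not matched by the gene's other probe, which changed by 0.23 at 24 h. Other probes of TPM4 (-1.03), HIGD1A (-0.83 and -0.73) and PACSIN2 (-0.41) fell at 24 h, by less than the probes used.

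Rises at 24 h were smaller. UBE2G2, a ubiquitin-conjugating enzyme of endoplasmic reticulum quality control, rose by 0.72 (SE 0.11, adjusted p = 0.0181), or 1.65-fold, while its other probe, above the noise limit on 7 of the 11 arrays, changed by 0.0051. DESI2 rose by 0.68 (SE 0.050, adjusted p = 0.000582) and SSU72, a phosphatase of the RNA polymerase II tail, by 0.59 (SE 0.065, adjusted p = 0.00456). The nucleoporin POM121C rose by 0.66 (adjusted p = 0.0493), the endosomal recycling factor RAB11FIP1 by 0.58 (0.0204), the mitochondrial ribosomal protein MRPL50 by 0.56 (0.00937), the small GTPase RAB23 by 0.56 (0.0326) and the exportin XPO4 by 0.52 (0.0455). POM121C has near-identical paralogs that its probe may read as well, and the other RAB11FIP1 probe changed by -0.00094. Leaving out 1 array of the 24 h groups ended several of these calls. Without 24 h MASTL siRNA replicate 3, SLC2A3 (-1.65), UBE2G2 (0.59), SSU72 (0.56) and MRPL50 (0.48) kept their direction and were no longer called. POM121C was lost in 10 of the 11 cases, with log2 changes of 0.54 to 0.78, and was kept only without 24 h control replicate 3. XPO4 was lost in 9 (0.45 to 0.59), with 24 h control replicate 3 and 48 h MASTL siRNA replicate 4 the exceptions. RAB23 was lost in 7 (0.53 to 0.60), the 5 arrays at 24 h and replicates 1 of the 48 h controls and 3 of the 48 h MASTL siRNA arrays. RAB11FIP1 was lost without any of the 5 arrays at 24 h (0.54 to 0.61).

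In all, 198 of 22144 features differed at 24 h at the adjusted threshold, 53 higher and 145 lower. Of these, 52 and 123 carried a gene symbol. Changes of at least 1.5-fold were mostly falls, with 4 features higher and 73 lower. The 4 were UBE2G2, DESI2, POM121C and SSU72. At least 2-fold, 13 were lower and 0 were higher. At an unadjusted p under 0.05, limma gave 2012 features, against 1107 by chance alone. The counts leaned on single arrays: they were 19 higher and 77 lower without 24 h control replicate 1, 15 and 52 without MASTL siRNA replicate 1, and 8 and 48 without MASTL siRNA replicate 3. The number higher alone dropped to 27 without 24 h control replicate 2 and to 33 without 48 h control replicate 1 or 48 h MASTL siRNA replicate 3.

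Several genes of the actin cytoskeleton changed by 24 h. VCL, which encodes vinculin, fell by 0.96 (SE 0.14, adjusted p = 0.0182). Another VCL probe, above the noise limit on all 11 arrays, changed by -0.56, and a further one, above it on 2, by -0.003. FHL2, a LIM-domain cofactor, rose by 0.30 (SE 0.037, adjusted p = 0.00792). Among 24 measured targets of MRTF and SRF, the actin-responsive transcription factors, 1 rose (FHL2) and 2 fell (TPM4 and VCL), the same 1 and 2 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.294). Of 27 genes of integrins and focal adhesions, VCL was the 1 that fell (1 higher and 1 lower adjusted over the list alone). That list had a median of -0.0022 and a mean of -0.0088, while the camera test pointed to higher (adjusted p = 0.76). In the 22 targets of the Hippo-pathway coactivators YAP and TAZ, ASAP1 fell by 0.92 (SE 0.13, adjusted p = 0.0145) and the phosphatase PTPN14 fell by 0.70 (SE 0.11, adjusted p = 0.0287), with 0 others called, adjusted over the list alone as well. The other PTPN14 probe, above the noise limit on all 11 arrays, changed by -0.11. The YAP and TAZ list had a median of 0.03 and a mean of -0.015 (camera adjusted p = 0.996). Of 7 mesenchymal markers SNAI2, the transcription factor Slug, rose by 0.34 (SE 0.049, adjusted p = 0.0176), the 1 call over all features and adjusted over the list alone. The other SNAI2 probe, above the limit on all 11 arrays, changed by 0.095. The mesenchymal list's median of -0.041 and mean of -0.002 stood against a camera test that pointed to higher (adjusted p = 0.929).

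Single arrays decided part of these member calls at 24 h. FHL2 lost its call without 24 h MASTL siRNA replicate 3 (0.27). VCL lost it without 24 h control replicate 1 or 2 or either 24 h MASTL siRNA array (-1.04 to -0.87), and ASAP1 without control replicate 1 or either MASTL siRNA array (-0.93 to -0.91). PTPN14 lost it without control replicate 1 or 2, either MASTL siRNA array or 48 h MASTL siRNA replicate 3 (-0.73 to -0.65). SNAI2 lost it without any 1 of the 3 controls or MASTL siRNA replicate 3 (0.25 to 0.36). TPM4 kept it in all 11 cases (-1.29 to -1.24).

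As lists, 6 gene groups were lower and 1 was higher at 24 h, among 25 tested. Cholesterol synthesis genes were lower, with 15 of 15 members negative and a mean log2 change of -0.34, though 0 of the 15 were called on their own, adjusted over the list alone as well (camera adjusted p = 0.00119, adjusted p = 0.79 with an estimated correlation). INSIG1 gave -0.85 (SE 0.47, adjusted p = 0.686) and MSMO1 -0.72 (SE 0.43, adjusted p = 0.729). Genes of G2, M and mitosis had a mean of -0.14 with 26 of 31 negative and 0 called by either adjustment (camera adjusted p = 0.012, adjusted p = 0.79 with an estimated correlation), and CDC20 gave -0.12 and UBE2C -0.18. Hypoxia and glycolysis genes had a mean of -0.19 with 18 of 20 negative (0 called over all features, 1 lower adjusted over the list alone, camera adjusted p = 0.0298, adjusted p = 0.79 with an estimated correlation). ENO1 gave -0.053 and LDHA -0.16. In the 9 chaperones of the endoplasmic reticulum, HYOU1 fell by 0.47 (SE 0.047, adjusted p = 0.00318), the 1 call by either adjustment, and the list mean was -0.14 (camera adjusted p = 0.0409, adjusted p = 0.79 with an estimated correlation). NF-kB and inflammatory cytokine genes (mean -0.16, 17 of 19 negative) and ATF4 and amino acid stress genes (mean -0.13, 11 of 14 negative) were lower, and the 7 NRF2 targets, genes of the oxidative stress response, were higher (mean 0.19, 0 negative). Each of these 3 had 0 called members by either adjustment and a camera adjusted p = 0.0447 (adjusted p = 0.79 with an estimated correlation). Members of these lists gave -0.51 for CXCL8, -0.48 for NFKBIA, -0.24 for ATF4, -0.25 for CEBPB, 0.30 for NQO1 and 0.30 for TXNRD1.

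At 24 h, 0 lists were called with the estimated correlation and 0 by fry, and 5 of the 25 by fry's test of change in either direction. Among the 5 were MRTF-SRF targets (adjusted p = 1.67e-06), YAP-TAZ targets (6.64e-05) and mesenchymal markers (0.0032), which camera did not call. The number of lists called dropped to 1 without 24 h control replicate 2. It was 4 without either 24 h MASTL siRNA array, 48 h control replicate 3 or 48 h MASTL siRNA replicate 3. The cholesterol synthesis list lost its call without 24 h control replicate 2 (adjusted p = 0.2635), whose group spread widely for INSIG1 (11.58 ± 1.06, SD, n = 3). The G2-M list lost its call without MASTL siRNA replicate 1 or control replicate 3 (0.081 to 0.094), the hypoxia list without control replicate 1 or 2 or MASTL siRNA replicate 3 (0.065 to 0.796) and the chaperone list without MASTL siRNA replicate 1 or control replicate 2 (0.129 to 0.264). The NF-kB list lost its call without MASTL siRNA replicate 1, control replicate 2 or 3, or replicate 3 of either 48 h group (0.054 to 0.433). For the ATF4 list it was control replicate 1 or 2, MASTL siRNA replicate 3 or replicate 3 of either 48 h group (0.055 to 0.600). For NRF2 targets it was either MASTL siRNA array, control replicate 2, replicate 3 of either 48 h group or 48 h control replicate 4 (0.052 to 0.433). With cyclic loess the NF-kB (0.0529), ATF4 (0.05002) and NRF2 (0.05002) lists were not called at 24 h.

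At 48 h, SLC2A3 was again the gene with the deepest fall, from 11.2 ± 0.34 (SD, n = 3) to 8.99 ± 0.24 (n = 3), 4.65-fold lower (log2 change -2.22, SE 0.20, adjusted p = 0.00142). KYNU, which encodes kynureninase of tryptophan breakdown, was 2.89-fold lower (log2 change -1.53, SE 0.23, adjusted p = 0.0118), and GTF2E2 2.52-fold lower (log2 change -1.33, SE 0.049, adjusted p = 2.41e-05). The genes with the largest rises were TCN1, a vitamin B12 carrier, which went from 7.95 ± 0.18 (n = 3) to 9.18 ± 0.33 (n = 3), 2.35-fold higher (log2 change 1.23, SE 0.17, adjusted p = 0.0077), and PAPPA, a protease of insulin-like growth factor binding proteins, 2.14-fold higher (log2 change 1.10, SE 0.18, adjusted p = 0.0171). The histone gene H2BC12 rose by 0.88 (adjusted p = 0.00647), the smooth muscle actin ACTG2 by 0.82 (0.00309), spermidine synthase SRM by 0.73 (0.0254), the granin SCG2 by 0.71 (0.000163), the phosphatase CTDSPL by 0.70 (0.0159) and the adhesion receptor ADGRL2 by 0.67 (0.0101). CDK6 (-1.27, adjusted p = 0.00237), VMA21 (-1.13, 0.000484), PACSIN2 (-1.08, 0.000506), DENR (-1.08, 0.000472) and HIGD1A (-1.05, 0.000472) fell. Histone and actin genes have close paralogs, so the probes of H2BC12 and ACTG2 may read more than 1 gene. The other DENR probe changed by -0.097.

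At 48 h, 518 of 22144 features differed, 230 higher and 288 lower, with 200 and 251 of them named. At least 1.5-fold, 23 were higher and 74 lower. At least 2-fold, 2 were higher (TCN1 and PAPPA) and 12 lower. With the replicate number as a block, which paired the arrays at 48 h, 936 features were higher and 933 lower, and with that block within each time 1398 and 1302. The counts were 110 higher and 140 lower without 48 h control replicate 1, 111 and 147 without control replicate 3, and 141 and 153 without MASTL siRNA replicate 3. The number lower alone dropped to 189 without MASTL siRNA replicate 1 and to 170 without MASTL siRNA replicate 4. Among the genes above, KYNU (-1.45 to -1.41) and CTDSPL (0.63 to 0.65) lost their calls without 48 h control replicate 1 or 3, and ADGRL2 without control replicate 3 (0.63). PAPPA lost its call without any 1 of the 3 controls or MASTL siRNA replicate 3 (1.03 to 1.14). SRM lost its call without any 1 of the 6 arrays at 48 h (0.66 to 0.79).

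The MRTF-SRF targets were higher as a list at 48 h, with members on both sides. ACTG2 and FHL2 (0.34, SE 0.033, adjusted p = 0.00179) rose, and TPM4 (-1.04, SE 0.080, adjusted p = 0.000506) and VCL (-1.01, SE 0.13, adjusted p = 0.00534) fell. These 2 rises and 2 falls among 24 measured genes became 8 and 2 when adjusted over the list alone. The list median was 0.19 and its mean 0.12 (camera adjusted p = 0.00205, adjusted p = 0.0821 with an estimated correlation), and fry called it as well (adjusted p = 0.0051). The 8 measured histone genes were higher, with 0 negative, a mean of 0.32 and 1 called member, H2BC12, or 2 adjusted over the list alone (camera adjusted p = 0.0115, adjusted p = 0.846 with an estimated correlation). The histone list lost its call without 48 h control replicate 1 (0.0812).

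ATF4 and amino acid stress genes were lower at 48 h, with a mean of -0.20 over 14 genes. ASNS, which makes asparagine, fell by 0.73 (SE 0.12, adjusted p = 0.0171) and ATF4, the transcription factor that drives this response, fell by 0.57 (SE 0.10, adjusted p = 0.0222), the 2 calls by either adjustment (camera adjusted p = 0.0115, adjusted p = 0.846 with an estimated correlation). Another ATF4 probe changed by 0.0057 and a further one by -0.43. Hypoxia and glycolysis genes had a mean of -0.20 with 18 of 20 negative and 1 fall by either adjustment, ANKRD37 at -0.61 (SE 0.12, adjusted p = 0.042; camera adjusted p = 0.0182, adjusted p = 0.98 with an estimated correlation). Endoplasmic reticulum chaperones had a mean of -0.18, with HYOU1, the 1 call of 9 genes by either adjustment, at -0.60 (SE 0.042, adjusted p = 0.000439; camera adjusted p = 0.0362, adjusted p = 0.926 with an estimated correlation). G2-M genes had a mean of -0.11 with 23 of 31 negative and 0 called by either adjustment (camera adjusted p = 0.0362, adjusted p = 0.98 with an estimated correlation), and CDC20 gave -0.062 and UBE2C 0.051. The G2-M list turned to higher without 48 h MASTL siRNA replicate 1 (adjusted p = 0.886) and lost its call without control replicate 4 (0.917). The hypoxia list lost its call without 48 h control replicate 1 or MASTL siRNA replicate 4 (0.385 to 0.396) and the ATF4 list without MASTL siRNA replicate 1 (0.0557). The chaperone list lost its call without either 24 h MASTL siRNA array, 48 h control replicate 1 or 3, or 48 h MASTL siRNA replicate 4 (0.057 to 0.245). ATF4 lost its call without any 1 of the 3 controls at 48 h or MASTL siRNA replicate 3 (-0.60 to -0.54), and ASNS without control replicate 3 or MASTL siRNA replicate 1 or 3 (-0.74 to -0.63). ANKRD37 lost its call in 9 of the 11 cases (-0.65 to -0.55) and was kept only without replicate 1 or 3 of the 24 h controls.

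Other called list members at 48 h followed the same signs as at 24 h. ASAP1 fell by 0.74 (SE 0.11, adjusted p = 0.0128) and PTPN14 fell by 0.66 (SE 0.10, adjusted p = 0.0121), and SNAI2 rose by 0.39 (SE 0.044, adjusted p = 0.00332). At 48 h the other PTPN14 probe changed by -0.10 and the other SNAI2 probe by 0.17. PTPN14 lost its call without 48 h MASTL siRNA replicate 3 (-0.64) and ASAP1 without that array or control replicate 1 (-0.74 to -0.71). Of 22 YAP and TAZ targets 0 rose and 2 fell by either adjustment, and of 27 integrin and focal adhesion genes 0 rose and 1 fell by either adjustment. The integrin list had a median of 0.029 and a mean of -0.0098, while its test pointed to higher. SNAI2 was the 1 call among 7 mesenchymal markers by either adjustment. These 3 lists were not called by camera (adjusted p = 0.899 for YAP and TAZ targets and for integrins and focal adhesion, and 0.919 for mesenchymal markers). Fry's test of change in either direction called all 3 (adjusted p = 0.000139, 0.0262 and 0.000249, in that order). The estimated correlation called 0 lists at 48 h and fry 1, and fry's test of change in either direction called 10 of the 25. Without 48 h control replicate 1, camera called 3 lists at 48 h in place of 6. Under the replicate block camera called the same 6 and 2 more at 48 h, NF-kB and inflammatory cytokines (lower, adjusted p = 0.0145, adjusted p = 0.721 with an estimated correlation) and leukocyte and endothelial markers (lower, adjusted p = 0.0386, adjusted p = 0.391 with an estimated correlation). With the block within each time it called the NF-kB list (adjusted p = 0.000866, adjusted p = 0.271 with an estimated correlation) and not the other.

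Averaged over both times, with 5 MASTL siRNA arrays against 6 controls, GTF2E2 gave the smallest adjusted p, at a log2 change of -1.27 (SE 0.037, adjusted p = 2.98e-06). The chaperone subunit PFDN1 (-0.76, SE 0.024, adjusted p = 3.29e-06), the adaptor subunit AP3M1 (-0.82, SE 0.028, adjusted p = 3.91e-06), AKTIP (-0.86, SE 0.033, adjusted p = 8.69e-06) and the spliceosome factor CWC27 (-0.65, SE 0.026, adjusted p = 9.82e-06) fell. DESI2 rose by 0.66 (SE 0.033, adjusted p = 3.51e-05), RAB40B by 0.24 and the corepressor CTBP1 by 0.42 (adjusted p = 8.63e-05 each), SCG2 by 0.45 (adjusted p = 0.000122) and SSU72 by 0.60 (adjusted p = 0.000204). These 10 genes kept their calls whichever of the 11 arrays was left out. Other probes above the limit on all 11 arrays gave the same signs with smaller sizes. At 24 h and 48 h they read -0.23 and -0.33 for AKTIP and -0.62 and -0.68 for AP3M1. For CTBP1 1 read 0.096 and 0.19 and another 0.18 and 0.23. Of 22144 features 1033 differed, 516 higher and 517 lower, 449 and 449 of them named, and at least 1.5-fold 11 were higher and 91 lower. With the replicate number as a block the counts were 1141 higher and 1110 lower. They were 292 and 283 without 24 h MASTL siRNA replicate 1 and 231 and 296 without 24 h MASTL siRNA replicate 3. The number higher alone was 338 without 24 h control replicate 1, 327 without 48 h control replicate 1, 321 without 48 h control replicate 3 and 336 without 48 h MASTL siRNA replicate 3.

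On average, 7 lists differed, 6 lower and 1 higher, and 0 of them were called with the estimated correlation. The MRTF-SRF list was higher (mean 0.076, 4 higher and 2 lower, or 10 and 2 adjusted over the list alone, camera adjusted p = 0.0083, adjusted p = 0.23 with an estimated correlation), and was the 1 list called by fry (adjusted p = 0.0314). Lower were the lists of G2-M (mean -0.13, camera adjusted p = 0.00753, adjusted p = 0.808 with an estimated correlation) and of hypoxia and glycolysis (mean -0.19, camera adjusted p = 0.00753, adjusted p = 0.808 with an estimated correlation). So were ATF4 and amino acid stress (mean -0.17, camera adjusted p = 0.00805, adjusted p = 0.716 with an estimated correlation) and endoplasmic reticulum chaperones (mean -0.16, camera adjusted p = 0.0206, adjusted p = 0.761 with an estimated correlation). NF-kB and inflammatory cytokines (mean -0.15, camera adjusted p = 0.0301, adjusted p = 0.808 with an estimated correlation) and cholesterol synthesis (mean -0.17, camera adjusted p = 0.0319, adjusted p = 0.808 with an estimated correlation) completed the 6. By either adjustment 2 members fell in the ATF4 list, 1 in the chaperone list, 1 in the hypoxia list and 0 in the other 3. Under the replicate block the cholesterol list was not called (adjusted p = 0.33) and the leukocyte and endothelial list was called lower (adjusted p = 0.021, adjusted p = 0.414 with an estimated correlation). The cholesterol list lost its call without either 24 h MASTL siRNA array, 24 h control replicate 2, 48 h control replicate 3 or 4, or 48 h MASTL siRNA replicate 1 (0.060 to 0.272). The NF-kB list lost it without 24 h MASTL siRNA replicate 1, 24 h control replicate 2 or 3, 48 h control replicate 1 or 3, or 48 h MASTL siRNA replicate 4 (0.059 to 0.293). The chaperone list lost it without 24 h MASTL siRNA replicate 1, 24 h control replicate 2, 48 h control replicate 1 or 48 h MASTL siRNA replicate 4 (0.062 to 0.071). The G2-M list lost it without 48 h MASTL siRNA replicate 1 or 48 h control replicate 4 (0.114 to 0.129). Without 24 h MASTL siRNA replicate 3, the ATF4 (0.0695) and hypoxia (0.170) lists were not called. The number of lists was 4 without either 24 h MASTL siRNA array or without 24 h control replicate 2.

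The genes lowered at 24 h were largely lowered at 48 h as well. Of the 145 features lower at 24 h and the 288 lower at 48 h, 136 were lower at both times, against 1.89 expected of independent lists. They included SLC2A3, CDK6, GTF2E2, PACSIN2, TPM4, VCL and MASTL. Another 40 were higher at both times, against 0.55 expected, among them FHL2, SNAI2, DESI2 and SSU72, and 0 were called in opposite directions. All 198 features called at 24 h had the same sign at 48 h, and 506 of the 518 called at 48 h had the same sign at 24 h. Across all features the log2 changes at the 2 times had a Pearson correlation of 0.724 and a Spearman correlation of 0.485. Genes are not independent replicates, so these correlations carry no p-value, and the 2 comparisons share no array. Both comparisons do use 1 estimate of the spread for each feature, so features of small spread are favoured at both times. The counts expected of independent lists can therefore be too low a yardstick. The Pearson correlation was 0.671 without 48 h control replicate 1, 0.660 without 24 h control replicate 2, 0.680 without 24 h control replicate 3, 0.620 without 24 h MASTL siRNA replicate 3, 0.671 without 48 h control replicate 3 and 0.638 without 48 h MASTL siRNA replicate 4. It was 0.660 with the replicate number as a block.

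**Figure D2:**
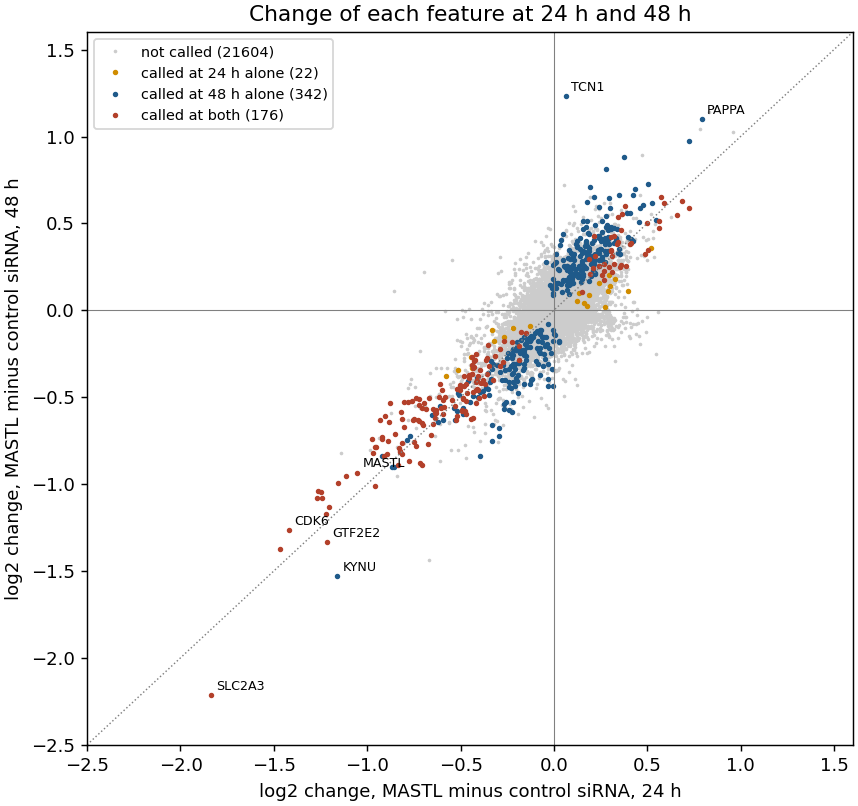
Log2 change after MASTL siRNA at 24 h (x axis) and at 48 h (y axis) for each of 22144 features, coloured by the time at which it was called. The 176 features called at both times all have the same sign at both times; 22 were called at 24 h alone and 342 at 48 h alone.

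No single gene's response to the MASTL siRNA passed the test of a difference between 48 h and 24 h. TCN1 differed by 1.17 (adjusted p = 1) and SCG2 by 0.52 (adjusted p = 0.237, the smallest of all), both picked out here after their values were seen. limma called 0 of 22144 features, with 670 at an unadjusted p under 0.05 against 1107 by chance, and with an intensity trend and robust moderation it called 1, SCG2 (adjusted p = 0.0366). Calls at 1 time and not at the other, such as KYNU and ACTG2 at 48 h, are therefore not shown to differ between the times. Nor do the 0 calls show that no gene differs. The fit leaves the pairing of the arrays at 48 h in its spread, which can hide differences, and 670 lies below the 1107. As lists, 4 groups changed more upwards at 48 h than at 24 h. The histone list had a mean difference of 0.27 with 0 of 8 negative (camera adjusted p = 0.00117, adjusted p = 0.872 with an estimated correlation) and the cholesterol synthesis list 0.34 with 0 of 15 negative (camera adjusted p = 0.00167, adjusted p = 0.983 with an estimated correlation). The MRTF-SRF list had 0.089 (camera adjusted p = 0.0018, adjusted p = 0.114 with an estimated correlation) and the interferon response list 0.15 (camera adjusted p = 0.0384, adjusted p = 0.983 with an estimated correlation). In each of them 0 members were called by either adjustment, and fry called 0 of the 25 lists. With the replicate number as a block, the cholesterol (0.754) and interferon (0.433) lists were not called, and 3 others were: G2-M (0.0235) and G1-S and DNA replication (0.0235) changed upwards and hypoxia and glycolysis (0.0287) downwards. These 3 calls were lost with an estimated correlation (adjusted p = 0.974 each). The cholesterol list lost its call without 24 h control replicate 2 (0.857) and the histone list without 24 h MASTL siRNA replicate 1 (0.0783). The interferon list lost its call without 24 h control replicate 2, 24 h MASTL siRNA replicate 3, 48 h control replicate 1 or 4, or 48 h MASTL siRNA replicate 1 or 3 (0.051 to 0.888). The number of lists was 2 without 24 h control replicate 2, 7 without 24 h control replicate 3 and 9 without 48 h MASTL siRNA replicate 4.

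Under the control siRNA, limma called 0 of 22144 features between 48 h and 24 h (smallest adjusted p = 0.0811), with 2186 at an unadjusted p under 0.05 against 1107 by chance. With an intensity trend and robust moderation 5 were called, CD74 (0.63), SP140 (0.38), KLRC3 (0.46), HSD11B1 (0.21) and SLC3A2 (-0.86), named after their values were seen. Without 24 h control replicate 2, 39 were called. With the replicate number as a block, which assumes that equal numbers at the 2 times share a deviation, 2567 were called, but same-numbered controls of the 2 times deviated with correlations of -0.0842 and -0.205.

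Genes of the PP2A-B55 and Greatwall axis, through which MASTL acts, were not called as a list by camera at either time. No member was called at either time in the fit without a block. By fry's test of change in either direction the list was called at 48 h (adjusted p = 0.0454) and not at 24 h (adjusted p = 0.665). Of 14 genes 0 rose and 0 fell by either adjustment (camera adjusted p = 0.929 at 24 h and 0.899 at 48 h), and PPP1CC gave 0.19 and 0.20 and PPP2CA 0.10 and -0.12 at 24 h and 48 h. Genes of G1, S and DNA replication had 0 called of 28 at both times (adjusted p = 0.996 and 0.899), with MCM7 at -0.019 and -0.082 and MCM3 at 0.079 and 0.13. At 48 h this list's median of -0.0038 and mean of 0.0017 differed in sign, as they did on average. Of 18 p53 targets, each read by its brightest probe, 0 were called (0.176 and 0.307). CDKN1A, the cell cycle inhibitor p21, gave -0.78 (SE 0.43, adjusted p = 0.69) and -0.45 (SE 0.39, adjusted p = 0.71), and ZMAT3 gave 0.32 and -0.076. The other 2 ZMAT3 probes gave -0.22 (SE 0.084) and -0.23 (SE 0.071) at 24 h. At 48 h they gave -0.36 (SE 0.075) and -0.43 (SE 0.063), and they did not enter the count of 0, which for this gene rests on the probe chosen. On average over both times 1 p53 target fell by either adjustment, RRM2B, a ribonucleotide reductase subunit named after its value was seen (-0.10, SE 0.023, adjusted p = 0.0384), and its call was lost in 9 of the 11 cases of 1 array left out (-0.12 to -0.085), the exceptions being 48 h MASTL siRNA replicate 1 and 48 h control replicate 4. The p53 list itself was not called on average (camera adjusted p = 0.145). Of 13 genes of the BCL2 family 0 were called (0.605 and 0.899), with BCL2L1 at 0.25 and 0.026 and BAX at 0.017 and 0.15. The BCL2 list's median and mean differed in sign, at 0.013 and -0.027 at 24 h and 0.025 and -0.0086 at 48 h. Of 13 immediate early genes 0 were called (0.102 and 0.899), with IER3 at -0.32 and -0.17 and KLF6 at 0.11 and -0.053. These calls of 0 at 24 h and 48 h were the same when adjusted over the list alone.

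Interferon response genes had 0 called of 27 at both times (camera adjusted p = 0.13 and 0.899), with ISG15 at 0.056 and 0.72 (SE 0.23, adjusted p = 0.175) and HERC5 at -0.19 and 0.032. At 48 h the NF-kB list (adjusted p = 0.177, CXCL8 -0.80, NFKBIA -0.29), the cholesterol list (0.899, INSIG1 0.11, MSMO1 -0.24) and the NRF2 list (0.899, NQO1 -0.025, TXNRD1 0.11) were not called and had 0 called members. At 24 h the 8 histone genes had 0 called members and were not called (0.961), with a median of -0.041, a mean of 0.046 and a test that pointed to lower, and H4C3 at -0.058 and H2BC12 at 0.38. The 23 genes of extracellular matrix and remodelling had 0 called (0.56 and 0.899), with TIMP1 at -0.26 and -0.36 and LAMC1 at -0.43 and -0.49. Targets of TGF-beta and SMAD had 0 called of 9 (0.0855 and 0.899), with BHLHE40 at -0.55 and -0.49 and TGFBI at -0.011 and 0.00086. Epithelial markers had 0 called of 10 (0.321 and 0.899), with KRT19 at -0.49 and -0.036 and EPCAM at 0.0023 and -0.086. With the replicate number as a block, 6 of the named genes that were not called at 48 h passed, at the same log2 changes: LAMC1, BHLHE40, MSMO1, XBP1, CD14 and PECAM1. With the block within each time, chosen after seeing the data, 13 passed at 48 h, these 6 and IER3, TIMP1, PPP1CC, CDKN1A, ISG15, CXCL8 and NFKBIA. In the fit without a block, adjusted over the list alone these counts stayed at 0.

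Markers of other cell kinds and reference genes served as background. Luminal breast markers had 0 called of 5 at both times, or 1 higher adjusted over the list alone at each (camera adjusted p = 0.56 and 0.647). XBP1 gave -0.23 and -0.38 and KRT8 -0.23 and -0.15, and the list's median and mean differed in sign, at 0.058 and -0.0097 at 24 h and 0.088 and -0.021 at 48 h. On average 1 luminal marker rose, ERBB2, named after its value was seen (0.25, SE 0.048, adjusted p = 0.0209), or 2 adjusted over the list alone, and its call was lost without replicate 1 of either 24 h group, 48 h control replicate 1 or 3, or 48 h MASTL siRNA replicate 3 (0.20 to 0.26). Leukocyte and endothelial markers had 3 measured genes of 8 and 0 called by either adjustment (0.102 and 0.56), with CD14 at -0.28 and -0.31 and PECAM1 at -0.097 and -0.24. On average all 3 were negative, with 0 called over all features and 2 lower adjusted over the list alone (camera adjusted p = 0.145). Of 9 reference genes 0 were called by either adjustment (0.929 and 0.979), with GAPDH at -0.12 and -0.072 and YWHAZ at -0.061 and -0.12. At 48 h the reference list had a median of -0.059 and a mean of 0.0023. The median log2 change of all features was 0.003 at 24 h and 0.0013 at 48 h.

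**Figure D3:**
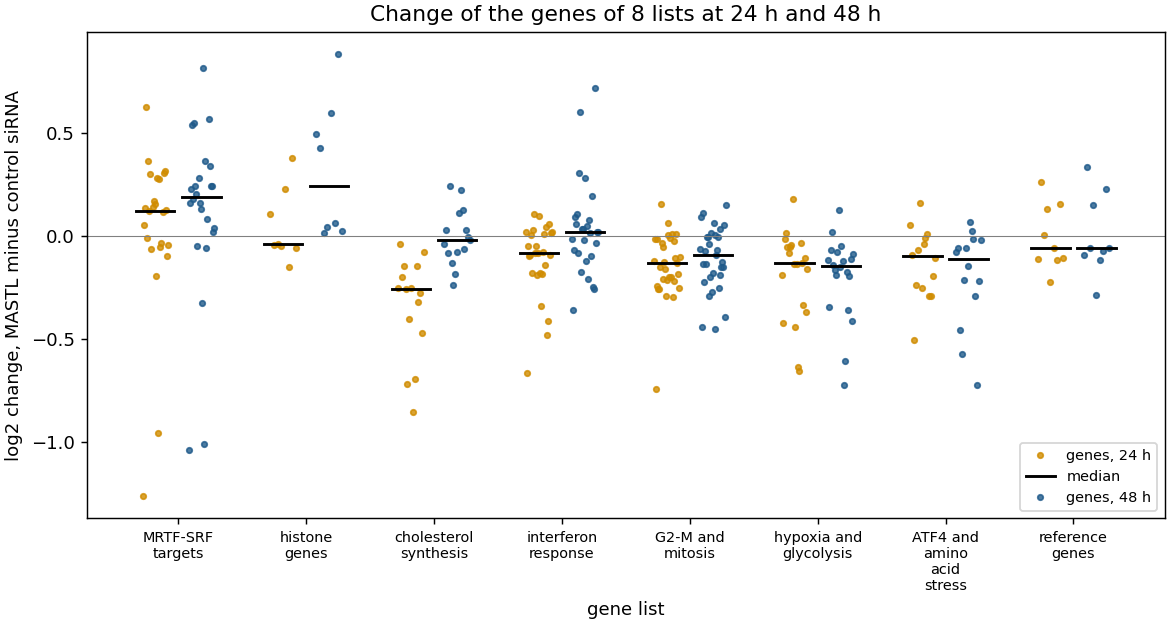
Log2 change (MASTL minus control siRNA) of each measured gene of 8 of the gene lists at 24 h and at 48 h, 1 point per gene, with the list's median as a line. All 15 cholesterol synthesis genes lie below 0 at 24 h, with a median of -0.26, and all 8 histone genes lie above 0 at 48 h, with a median of 0.24.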

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

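Of the tests below, those of the correlation between a list's genes were chosen after the result was seen, and the others before. The criteria for the control arrays, for single arrays and for genes varying together were changed after the values were seen.

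4 gene lists differed between the times in their response to the MASTL siRNA, by camera's test of the 48 h minus the 24 h change: histone genes (adjusted p = 0.00117), cholesterol synthesis (0.00167), MRTF-SRF targets (0.0018) and interferon response (0.0384). With the estimated correlation 0 of the 4 calls remained (adjusted p = 0.872, 0.983, 0.114 and 0.983). No outlier test was run within groups, which held 2 or 3 arrays. The 4 results are weighed together as 1 pattern.

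For the cholesterol list the values point to 1 array, while the call of the interferon list was borderline. The mean change of the cholesterol list went from -0.34 at 24 h to -0.005 at 48 h, but the unadjusted camera p reached 0.474 without 24 h control replicate 2 and was 0.283 with the estimated correlation, so this difference may come from 1 array whose genes vary together. The mean of the interferon list went from -0.11 to 0.034, with camera p = 0.436 without 48 h MASTL siRNA replicate 3 and p = 0.363 with the estimated correlation. Its camera adjusted p was 0.0384, and the call was lost without any 1 of 6 arrays (adjusted p 0.051 to 0.888). The interferon call therefore points to no array in particular, and genes varying together stays open for it. The controls gave 11.2% of the cholesterol difference (95% interval over the genes -15% to 37.4%) and -78.2% of the interferon difference (-173% to 16.7%), but intervals over genes leave out the spread between arrays. Over arrays, the change with time under MASTL siRNA was 0.299 (95% interval -0.335 to 0.932) for the cholesterol list and 0.258 (-0.118 to 0.635) for the interferon list, so a change in the control arrays alone cannot be told apart for either.

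For histone genes, whose mean change went from 0.046 to 0.32, the unadjusted p was at most 0.0125 with 1 array left out, but the adjusted p reached 0.0783 without 24 h MASTL siRNA replicate 1, so the part of that array stays open. The controls gave 129% of the difference (58.8% to 200%) and changed with time by -0.351 (95% interval over arrays -0.6 to -0.102). Under MASTL siRNA the change was -0.08 (-0.359 to 0.199), so the interval was clear of 0 in the controls only. The p was 0.0698 with the estimated correlation, so genes varying together stays open as well. For MRTF-SRF targets, whose mean went from 0.032 to 0.12, 1 array does not account for the difference (highest p 0.00348, adjusted 0.029). Genes varying together are argued against by the estimated correlation itself, -0.0102 (-0.024 to -0.0042 with 1 array left out), although with it the p was 0.00455 and the call was lost on adjustment (0.114). The controls gave 130% of the difference (interval over the genes 10.4% to 250%) and changed with time by -0.116 (95% interval over arrays -0.166 to -0.0664). Under MASTL siRNA the change was -0.027 (-0.0829 to 0.0289), so here too the interval was clear of 0 in the controls only. These shares divide the difference itself between the control and MASTL siRNA arrays, and an interval that includes 0 does not show absence of change. An effect of the MASTL siRNA would also give unlike changes with time, so the shares cannot decide the cause. For both lists a biological difference between the times remains an open hypothesis that was not tested further.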

How the results depend on the processing

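The filters above all 11 arrays and at the 99th percentile, and the replicate block within each time, were chosen after seeing the data. Signal over background limits the dim probes, MASTL among them. Directions held under every alternative run for the 62 called results of genes taken by the naming rule, and for 24 called lists with 1 exception: the G2-M list at 48 h turned without 48 h MASTL siRNA replicate 1 (adjusted p = 0.886, range over the left-out arrays and numbers 1.23e-06 to 0.9173). The calls held less well than the directions. Most of these gene calls were lost without replicate 1 or without replicate 3 in all groups, fits that leave 1 MASTL siRNA array at 24 h. Unless a construction is named, the cause was not tested.

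Called lists at 24 h numbered 3 above the limit on all 11 arrays, 4 at the 99th percentile and 4 with cyclic loess, against 7. With the estimated correlation 0 lists were called at 24 h, 48 h, on average and for the difference, and by fry 0, 1, 1 and 0. Array weights ended the calls of G2-M at 48 h (0.281) and of 4 others. With only the 2 groups of a comparison, which leaves fewer arrays to estimate the spread, 4 features were higher (SSU72, RAB11FIP1, CTBP1 and RAB23) and 54 lower at 24 h, and 177 lower at 48 h, and 24 of 52 gene calls were lost. With the replicate block, counts higher and lower were 106 and 255 at 24 h, 936 and 933 at 48 h, and 1141 and 1110 on average, control time gave 2567, the correlation of the times was 0.6603 and 2 lists were called at 24 h. POM121C and SNAI2 at 24 h and 9 lists, 6 of them at 24 h, lost their calls under this block, 6 genes gained one, and lists gained 1 at 24 h (G1-S, whose test turned to lower), 2 at 48 h, 1 on average and 3 for the difference. With an estimated correlation 0 lists were called under this block in any comparison (camera adjusted p = 0.7 for G1-S at 24 h). The block changed no other call of these genes and lists. At 24 h and between times the arrays share only a number (24 h correlations 0.104 and 0.47). With the replicate block within time the counts were 240 and 405, 1398 and 1302, and 1547 and 1437 with a correlation of 0.6603, 19 gene calls were gained (6 at 24 h: IER3, LAMC1, CDKN1A, NFKBIA, BHLHE40 and INSIG1) and SNAI2 at 24 h lost, lists gained 2, 1, 1 and 3 calls and lost 3, 0, 1 and 1 (24 h, 48 h, average and difference), and control time cannot be estimated apart from the block. With a random replicate block (correlation 0.184) they were 89 and 224, and 450 and 444, with 775 higher on average. Array weights gave 85 higher at 24 h, 487 and 501 at 48 h and 780 higher on average. An intensity trend with robust moderation gave 31 higher at 24 h, 1 for the difference (SCG2) and 5 for control time, and FHL2 lost its calls.

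By construction, at least 1.5-fold left 4 and 73 at 24 h, 23 and 74 at 48 h, and 11 and 91 on average. An adjusted p under 0.01 left 9 and 60 at 24 h and 79 and 112 at 48 h, and one under 0.1 gave 103 higher at 24 h and 461 and 447 at 48 h.

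Leaving out each array, or each replicate number in all groups, gave 0 to 53 higher and 0 to 162 lower at 24 h, 0 to 261 and 0 to 309 at 48 h, and 4 to 526 and 31 to 559 on average. Control time ranged from 0 to 47, the difference between times stayed at 0, and the correlation ranged from 0.606 to 0.733. Called lists ranged from 1 to 9 at 24 h, 3 to 7 at 48 h, 4 to 7 on average and 2 to 9 for the difference. MASTL ranged from -1.122 to -0.9988 at 24 h and -0.9902 to -0.832 at 48 h. Its call was lost only without replicate 1 or 3 in all groups, which leaves 1 MASTL siRNA array at 24 h, and a lone array is then assumed to vary like the others.

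No filter ended the calls of POM121C, XPO4 and ANKRD37 and of the interferon list (0.0502), and every probe as a feature that of NRF2 targets at 24 h (0.0538). Cyclic loess moved the median change of all features by at most 0.00239. Not run were no background correction, an offset of 50 and filters on detection p, which need signals not used here, a chip block, and seed matches. Median scaling moves nothing, since the column medians are equal, and the series' own values are the ones tested. The random block and the size and adjusted p thresholds gave no list tests.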

Other observations

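Of the tests in this part, those of the siRNA's action on other transcripts and of a shared culture or processing step were chosen after the result was seen, and the others before.

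The lowering was broad. Besides MASTL, 135 features were lower at both times, 114 of them named genes, with median log2 changes of -0.61 at 24 h and -0.55 at 48 h. They include GTF2E2, PFDN1, AP3M1, AKTIP and CWC27 (at 24 h and 48 h, GTF2E2 -1.22 and -1.33, PFDN1 -0.88 and -0.64, AP3M1 -0.81 and -0.83, AKTIP -0.84 and -0.89, CWC27 -0.65 and -0.66). A fault of single probes as the whole cause is argued against: of 53 other probes for 43 of these genes, 51 were also lower at 48 h, or 96.2% (exact binomial 95% interval 87% to 99.5%), against 48.8% of all probes past the filter, though their median change was -0.195 against -0.55 for the features themselves, so the size of the fall stays open. That interval takes the probes as independent. Some share a gene and all share the same arrays, so it is too narrow. The median difference between the 48 h and 24 h changes was 0.0569 (quartiles -0.022 to 0.14), against 0.12 for MASTL itself, and 43 of the 135 fell further at 48 h, but a call at both times was required of these features, which favours a small difference, so this value decides nothing. With 1 siRNA and no search of 3' untranslated regions, action of the siRNA on transcripts other than MASTL and a response to loss of MASTL cannot be told apart, so such action may account for part of the genes lowered in these data.

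More genes were called at 48 h with the replicate number as a block. Arrays of the same number at 48 h deviated together, with a lowest correlation of 0.549, which is consistent with a culture or processing step shared by same-numbered arrays, a step the labels do not describe.

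Other splits of the arrays bear on the counts. At 48 h, the real split of the 6 arrays called 518 features and the highest of the other splits 0. With 1 of 10 splits giving as many, the splits are too few for a share under 0.05. Of the 10, 4 part all 3 same-numbered pairs, and the other 3 of these called 0. For the average over both times, 1 of 100 splits drawn from 200 gave as many features as the real 1033, the highest other giving 320. Of the 100, 40 part all 3 same-numbered pairs at 48 h, among them the real split and the one with 320, and 1 of these 40, the real split, gave as many. The 60 that part 1 pair called at most 2 features, but they do not keep the pairing of the real split. Splits that mix the groups also carry the effect of the siRNA in their spread, which lowers their counts. The 40 splits argue against chance for that count without excluding it. Gene lists fared otherwise. At 48 h, 5 of 10 splits called as many as the real 6 lists, with a highest other of 10. Those 10 splits are too few for a share under 0.05, and the 6 splits that part 1 pair called 4 to 10 lists while the other 3 that part all 3 pairs called at most 1. For the average, 36 of 100 splits called as many as the real 7 lists, with a highest other of 14, so chance cannot be excluded for the list calls. Of those 36, 29 part 1 pair and 7, the real split included, part all 3, where the highest other was 9. Under control siRNA, the real count was 0, so 10 of 10 splits reach it whatever they call (highest other 0), and the splits decide nothing there.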
